A study of Mus musculus with 12 samples.

How the data were processed

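Total RNA was measured by RNA sequencing in 12 libraries from microdissected mouse pancreatic ductal adenocarcinomas. Of these, 6 carry the genotype label Hnf4a +/+ and are called Hnf4a-positive here. The other 6 carry the genotype label Hnf4a F/F and are called Hnf4a-deleted. Per the labels' protocols, RNA was extracted from stained, formalin-fixed and paraffin-embedded sections with a Qiagen miRNeasy kit, and libraries were made with a stranded Illumina TruSeq kit after ribosomal RNA depletion. Such RNA is fragmented, and a total RNA library also holds unspliced and small structural transcripts. Per the submitters' processing notes, STAR 2.5.4a, featureCounts 1.6.3 and DESeq2 1.22.2 were used. The deposited values are raw counts per gene, which the authors did not normalize before deposit: they are whole numbers, and their sums differ between libraries. The strand setting, the annotation release and the handling of reads with several alignments are not given in the sources used here. The notes name the human build GRCh38, which is at odds with the mouse Ensembl gene identifiers of the table, so the build behind the counts is not established. Gene symbols, biotypes and coordinates were taken from the mouse GENCODE M21 annotation on GRCm38, in which 53620 of the 53801 identifiers (99.7%) were found. Coordinates printed in the text are those of that annotation.

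Each column of the count table was assigned to a sample by its name and each sample to a group by its genotype label. Sample titles carry 2 number prefixes, 14224 (called the first prefix) and 14687 (the second), each with 3 libraries of each genotype. What the prefix stands for is not stated, so it was treated as a possible batch. Replicate numbers were given in accession order and pair no samples. No label says that the tumours came from separate animals, so p-values measure only the spread between these libraries.

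Total counts ranged from 9541410 to 17568222 per library. No 2 libraries of a genotype were duplicates: the chi-square of their counts per degree of freedom was 36.9 or more for every pair, far above sampling noise. Genes were kept by edgeR's filterByExpr with the genotype groups (minimum count 10, minimum total 15), which left 16234 genes, and library sizes were scaled by TMM. The genotype difference was tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, with the title prefix as covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are Hnf4a-deleted over Hnf4a-positive, with standard errors (SE) from the same fit; adjusted p-values of single genes are from this test. Levels are TMM-scaled CPM, as mean ± SD over 6 libraries. The same test was run within each prefix (3 against 3) and for the genotype-by-prefix interaction.

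The 28 gene lists were fixed before the data were examined. They cover epithelial identity, transcription factors, metabolism, proliferation and signalling, and the other cell types a dissected tumour can hold. Some genes stand in several lists, so the lists are not independent. Each list with 3 or more measured genes (27 lists) was tested against the other genes with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the lists. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Fits to part of the libraries filtered genes anew. Their list means and list tests can therefore cover other members than the fit of all libraries. Mean log2 CPM (prior count 2) of 11 cell type marker lists was compared between genotypes with a two-sided exact permutation test over all 924 regroupings of 6 against 6.

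Genes are named by a rule fixed before the data were examined: Hnf4a, Six1, Six4, Hnf1a, Gata6 and Foxa1 always; the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold, with 5 CPM or more in the higher group, the same sign within both prefixes and a symbol that is not a model name; up to 4 members of each list with the smallest p; and at most 4 interaction genes. Genes named outside the rule are said to be so.

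The procedure was tested on simulated counts for the same 16234 genes, in which 200 genes were changed. It recovered 36% of the genes changed 2-fold, 72% at 4-fold, 84% at 8-fold and 92% at 16-fold (50 genes each), with 5 false calls among 147. In simulated lists, both planted lists were found and no other was called, but the simulated genes are not correlated, so this does not measure false list calls. With the preset correlation, 99 other splits of the real libraries, balanced over the prefixes, called 2 to 18 lists each. At this depth and spread most 2-fold changes go undetected.

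Alternatives fixed before the data were examined were no prefix term, DESeq2's size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 6 libraries, DESeq2 1.42.0, limma voom with library weights, a test against a 1.5-fold change, the acinar or the fibroblast marker mean as covariate, removal of mitochondrial, acinar, globin and immunoglobulin genes, each prefix alone, and leaving out each library in turn. Added after seeing the data were a covariate made of the mean of 9 pan-epithelial genes (Krt8, Krt18, Krt19, Epcam, Cdh1, Cldn7, Esrp1, Ocln and Grhl2), a fit without the 2 libraries with the lowest value of it (Hnf4a-deleted replicates 3 and 6), a fit of protein-coding genes only, the estimated correlation in list tests other than that of all libraries, and all alternatives of the interaction test.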

Results

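The expression profiles of 12 microdissected autochthonous pancreatic ductal adenocarcinomas (PDAC) of mixed 129/B6 mice were measured by total RNA sequencing of fixed sections. In 6 tumours Hnf4a was intact, and in 6 it had been deleted at tumour initiation. Hnf4a encodes a nuclear receptor transcription factor of liver, gut and pancreatic epithelium, and the comparison asked how PDAC that forms without it differs from PDAC that retains it. Libraries held 9541410 to 17568222 counts. Between 23202 and 26309 genes were detected in a library. Mitochondrial ribosomal RNA took 2.47% to 8.88% of the counts. On the first principal component (30.0% of the variance of the 1000 most variable genes), the positive tumours lay between -37.5 and -11.2 and the deleted tumours between -3.09 and 46.2, with Hnf4a-deleted replicate 5 nearest to the positive tumours.

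Hnf4a itself (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910 in GENCODE M21 on GRCm38) was lower in every deleted tumour than in every positive one. It averaged 222 ± 35.6 CPM (SD, n = 6) in the positive tumours and 28.2 ± 15.6 CPM (n = 6) in the deleted ones. The log2 fold change was -3.08 (SE 0.29, edgeR adjusted p = 0.000953). It was -3.60 among the 3 against 3 libraries of the first prefix and -2.59 in the second. With only the first prefix fitted, the gene did not pass the threshold (adjusted p = 0.0865). The counts left in the deleted tumours amounted to 11.8% of the positive level (95% interval 7.94% to 17.5%). The counts cover the whole gene, and which exons were removed is not given in the sources used here.

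Loss of Hnf4a went with a lower level of genes of gut-like and hepatic epithelium. Of 16234 genes tested, 70 were lower and 19 higher in the deleted tumours, with a median fold of 8.07 among the lower genes and 4.14 among the higher. The largest decrease was that of Apob, the apolipoprotein of chylomicrons and low-density lipoprotein, at 1047 ± 1156 CPM in positive and 4.04 ± 1.47 CPM in deleted tumours (log2 fold change -7.91, SE 0.70, adjusted p = 0.0019), and its positive mean was 600 CPM without Hnf4a-positive replicate 6. Vil1, the brush border protein villin, fell from 85.8 ± 42.1 to 1.40 ± 0.97 CPM (log2 fold change -5.97, SE 0.58, adjusted p = 0.00186). Hnf1a, a transcription factor of liver and gut that acts in a circuit with HNF4A, fell from 13.2 ± 5.46 to 0.484 ± 0.298 CPM (log2 fold change -4.73, SE 0.43, adjusted p = 0.000953).

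**Figure D1:**
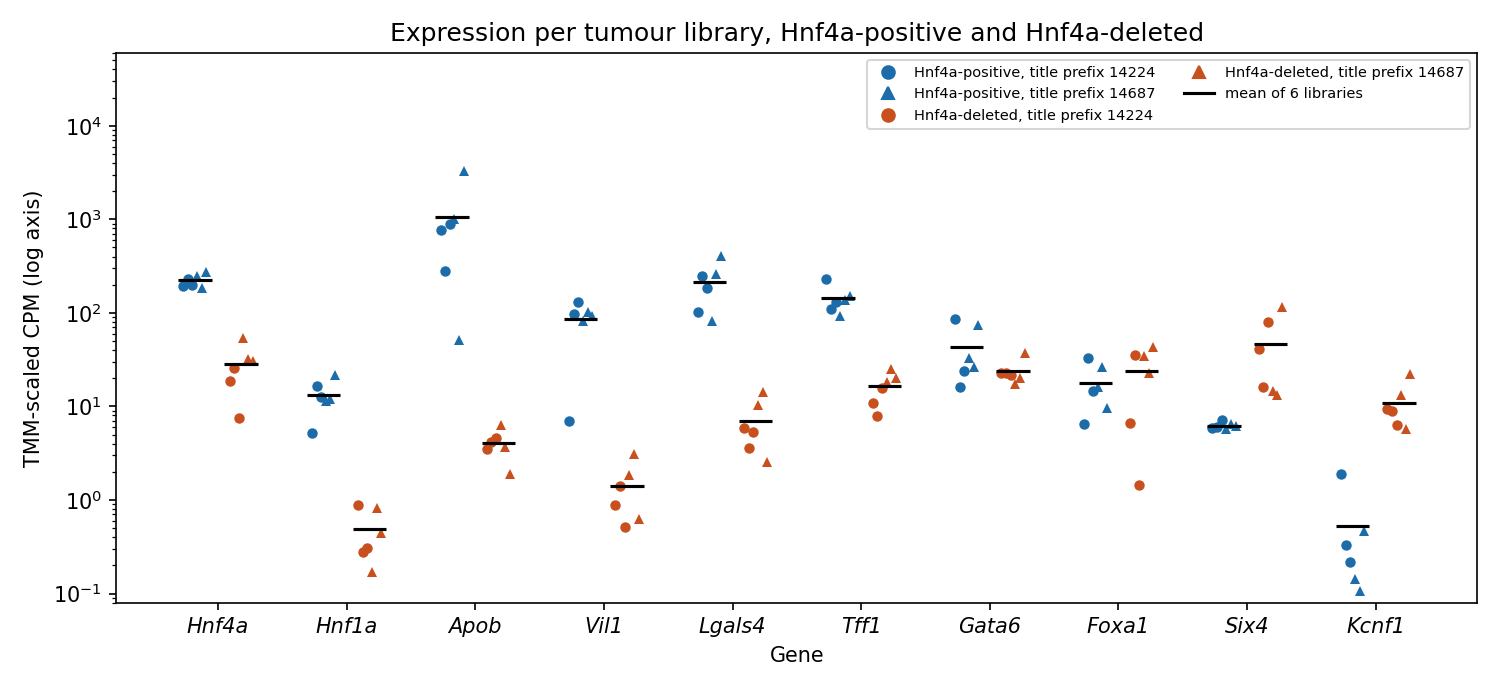
Each point is the TMM-scaled CPM (log axis) of 1 library for the gene on the horizontal axis, with genotype by colour, title prefix by shape and the mean of 6 libraries as a line. Hnf4a, Hnf1a, Apob, Vil1, Lgals4 and Tff1 show no overlap between genotypes, Gata6 and Foxa1 overlap, and Six4 lies between 13.1 and 115 CPM in the deleted tumours against 5.71 to 7.16 CPM in the positive ones.

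The other genes with the largest decreases were Gimd1 (log2 fold change -7.12), Anks4b (-6.77), an adaptor of the intermicrovillar complex of the brush border, Tm4sf20 (-6.31), Dnajc22 (-6.12), Pklr (-6.03), the pyruvate kinase of liver and red cells, Slc17a4 (-5.63), a phosphate transporter family member, Anxa13 (-5.25), an annexin of intestinal epithelium, and Myo15b (-5.13). Their edgeR adjusted p-values lay between 0.000563 and 0.00697, and the 6 deleted tumours lay below the 6 positive tumours for each of them. Several were close to absent in the deleted tumours: Anks4b averaged 0.114 CPM (0.0126 CPM without Hnf4a-deleted replicate 5) and Tm4sf20 0.113 CPM there. Over all 16234 genes tested, 136 were lower and 75 higher in every deleted tumour than in every positive one, together 1.30% of the genes, where chance gives 0.216%.

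Fewer genes passed the threshold as higher, although at an unadjusted p under 0.05 there were 967 higher and 902 lower genes. Kcnf1, a modifier subunit of voltage-gated potassium channels, rose from 0.523 ± 0.674 (0.254 without Hnf4a-positive replicate 1) to 10.9 ± 6.08 CPM (log2 fold change 4.43, SE 0.64, adjusted p = 0.0139). Ar, the androgen receptor, rose from 15.3 ± 8.50 to 63.3 ± 16.5 CPM (log2 fold change 2.05, SE 0.33, adjusted p = 0.0213). Six4, a homeobox gene of muscle, kidney and sensory development, was at 6.25 ± 0.53 CPM in positive and 46.7 ± 42.3 CPM in deleted tumours (log2 fold change 2.90, SE 0.52, adjusted p = 0.0419). The others were Klhdc8a (3.62), Miat (3.40), a long noncoding RNA, Greb1 (2.88), a gene induced by oestrogen receptor, Trbc2 (2.58), a constant segment of the T cell receptor beta chain, Sema3d (2.29), a secreted semaphorin, P3h2 (2.11), a collagen prolyl hydroxylase, and Map2 (2.05), a neuronal microtubule protein, with adjusted p-values between 0.0282 and 0.0439. Six1, the gene next to Six4, did not pass the filter on low counts. It lay between 0.16 and 1.55 CPM in the positive tumours and between 0.48 and 49.6 CPM in the deleted ones, with a mean of 13.1 ± 19.4 CPM in the latter (5.75 CPM without Hnf4a-deleted replicate 6). Six4 passed the threshold under 12 of 28 alternative settings (adjusted p up to 0.296, log2 fold change 1.68 to 3.10). It missed the threshold when any 1 of the 6 positive libraries or Hnf4a-deleted replicate 1, 3 or 6 was left out (adjusted p 0.064 to 0.128). Kcnf1 missed it without Hnf4a-positive replicate 6 (adjusted p = 0.0606), Ar without Hnf4a-positive replicate 4 or 6 or Hnf4a-deleted replicate 1 or 4 (adjusted p 0.0505 to 0.0747), and the other higher genes named here on leaving out any of 8 to 11 single libraries of the 12.

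All 89 changed genes had the same sign within both prefixes, but they were called in a fit of these same libraries, which favours equal signs. Fitted alone, with 3 libraries a side, the first prefix gave 0 higher and 2 lower genes by edgeR (976 and 878 at an unadjusted p under 0.05), and the second 16 and 16. Of the 16 higher genes of the second prefix, 1 was among the 19 called with all libraries. Of its 16 lower genes, 11 were among the 70. The count of higher genes depended on single libraries. It was 4, 3, 5, 9 and 1 without Hnf4a-positive replicate 1, 2, 4, 5 and 6, and 7, 12, 29 and 10 without Hnf4a-deleted replicate 1, 4, 5 and 6. The count of lower genes was 41 without Hnf4a-positive replicate 6 and 107 without Hnf4a-deleted replicate 5. With the acinar marker mean as a covariate, 29 lower genes and 1 higher gene passed the threshold.

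Gastrointestinal and hepatic target genes of HNF4A fell as a group. Of 14 measured members, 7 fell and none rose over all genes tested, and 12 fell adjusted over the list alone. The mean log2 fold change was -3.53. Over the members measured there, it was -3.74 and -3.85 within the first and second prefix. Besides Apob, Vil1, Anks4b and Hnf1a, these included Lgals4, the gut lectin galectin-4 (log2 fold change -4.97, SE 0.43), and Cdh17, the liver-intestine cadherin (-3.74, SE 0.37). The list test gave adjusted p = 3.57e-43 with the preset correlation and 0.000836 with an estimated correlation. Genes of the intestinal brush border and of goblet cells fell in 4 of 11 members and in 7 of 11 adjusted over the list alone, with a mean log2 fold change of -2.52 (-2.47 and -2.49 within the prefixes; adjusted p = 2.28e-18, and adjusted p = 0.000877 with an estimated correlation). The 4 were Vil1, Lgals4, Cdh17 and Myo1a, a brush border myosin (-3.07, SE 0.58), whose call ended on leaving out any of 11 single libraries, all but Hnf4a-deleted replicate 1 (adjusted p 0.062 to 0.111).

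Genes that mark the classical subtype of PDAC and genes of gastric epithelium were also lower in the deleted tumours. Of 13 measured classical genes, 4 fell, and 10 fell adjusted over the list alone, with a mean log2 fold change of -2.33 (-2.77 and -1.93 within the prefixes). The 4 were Lgals4, Cdh17 and Myo1a, which also stand in the brush border list, and Tff1, which also stands in the gastric list. Tff1, a trefoil peptide of gastric surface mucus, fell from 143 ± 49.0 to 16.4 ± 6.33 CPM (log2 fold change -3.17, SE 0.28). The list test gave adjusted p = 1.80e-28, and adjusted p = 0.000877 with an estimated correlation. Of 16 gastric genes, Tff1 and Vsig1, a gastric adhesion protein (-4.09, SE 0.47), fell, and 10 fell adjusted over the list alone (mean log2 fold change -2.03, adjusted p = 4.88e-18, and adjusted p = 0.00412 with an estimated correlation). Anxa10 was at 117 ± 62.9 CPM in positive and 16.9 ± 18.7 CPM (10.1 CPM without replicate 4) in deleted tumours without passing the threshold over all genes (log2 fold change -2.83, adjusted p = 0.134).

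No shift with genotype was detected in the 11 measured genes of the basal-like subtype. None passed the threshold over all genes or adjusted over the list alone. Their mean log2 fold change was 0.05, while the list test pointed down (adjusted p = 0.745). Dhrs9 had a log2 fold change of 1.56 (SE 0.70, adjusted p = 0.43) and Areg one of -1.14 (SE 0.41, adjusted p = 0.305). None of the 12 squamous epithelium genes passed either (mean log2 fold change -0.40, list adjusted p = 0.0583), with Krt14 at -1.60 (SE 0.64, adjusted p = 0.37). The squamous list passed without Hnf4a-positive replicate 6 or Hnf4a-deleted replicate 2 or 4 (adjusted p 0.0111 to 0.0242) and in the first prefix alone (0.0426), but in none of these with an estimated correlation (adjusted p 0.15 to 0.341).

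Among 19 endodermal transcription factors, Hnf1a was the only one that fell over all genes tested, and 5 fell and 1 rose adjusted over the list alone. The mean log2 fold change was -0.93, with -1.24 and -0.68 within the prefixes (adjusted p = 4.48e-09, and adjusted p = 0.0264 with an estimated correlation). With an estimated correlation the list did not pass without Hnf4a-positive replicate 3 (mean -0.82, adjusted p = 0.0547), with the acinar covariate (mean -0.71, adjusted p = 0.12), with the pan-epithelial covariate (mean -0.85, adjusted p = 0.0511) or within either prefix (adjusted p = 0.122 and 0.339). In the second prefix alone the HNF4A target, brush border, classical and gastric lists did not pass with an estimated correlation either (adjusted p = 0.101 each). Onecut2, abundant at 2037 ± 407 CPM in positive tumours, was at 823 ± 460 CPM in deleted ones (log2 fold change -1.46, adjusted p = 0.107), and Foxa3 had a log2 fold change of -1.58 (adjusted p = 0.116). Gata6 (43.2 ± 29.1 against 23.7 ± 6.82 CPM, log2 fold change -0.86, adjusted p = 0.435) and Foxa1 (17.7 ± 10.1 against 24.1 ± 16.9 CPM, log2 fold change 0.33, adjusted p = 0.885) did not pass the threshold. The point estimate of Foxa1 was -0.31 in the first prefix and 0.94 in the second.

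**Figure D2:**
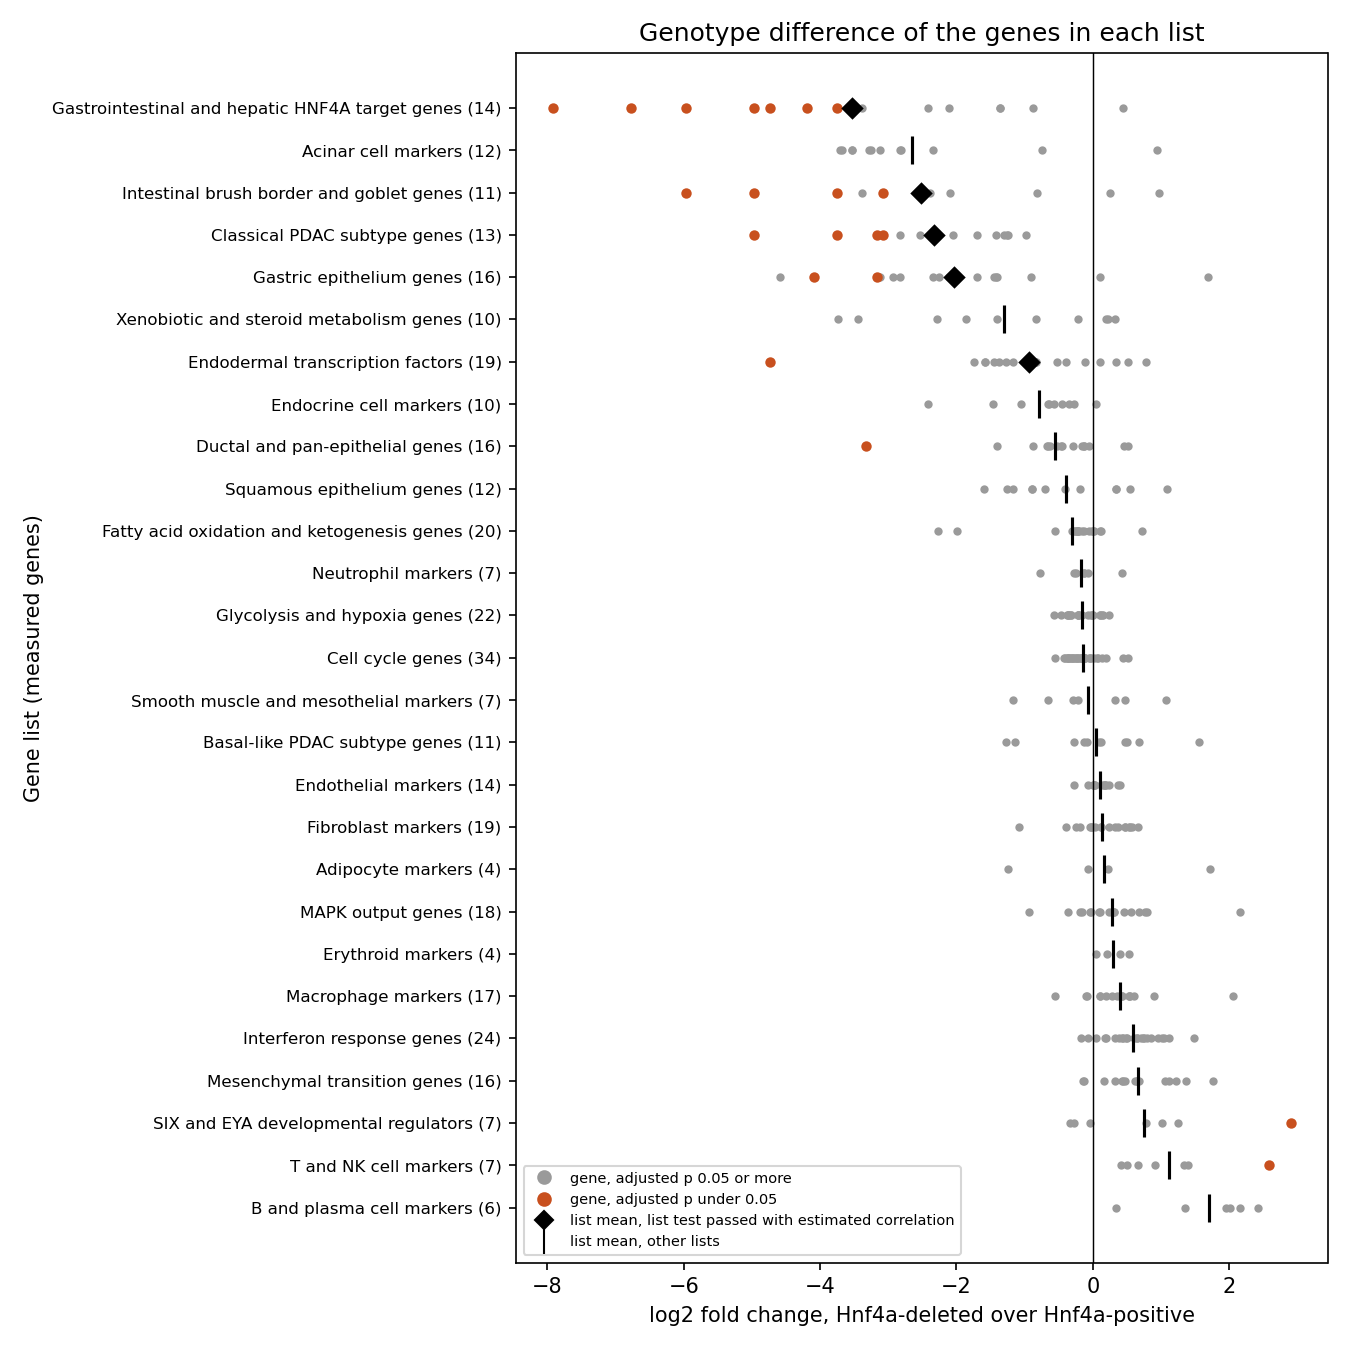
Each row is a gene list with its number of measured genes, each point the log2 fold change (Hnf4a-deleted over Hnf4a-positive) of 1 gene, coloured where its adjusted p is under 0.05, and the black mark the list mean, a diamond where the list test also passed with an estimated correlation. The 5 diamonds lie between -3.53 and -0.93, and no list above 0 has one.

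The other epithelial and metabolic lists that were called lost the call with an estimated correlation. Of 16 ductal and pan-epithelial genes, only Cftr, the apical chloride channel of ducts, fell (175 ± 97.6 to 17.7 ± 15.6 CPM, log2 fold change -3.33, SE 0.51, adjusted p = 0.0208; 0.0502 without Hnf4a-positive replicate 5 and 0.0557 without Hnf4a-deleted replicate 4), and 2 fell adjusted over the list alone. The list mean was -0.55 (adjusted p = 8.47e-05, but adjusted p = 0.363 with an estimated correlation). It was -0.33 without Hnf4a-deleted replicate 3 and -0.30 with the acinar covariate, and the list was not called in the second prefix (adjusted p = 0.2). The cadherin gene Cdh1 (-0.88, adjusted p = 0.376) and the keratin gene Krt8 (-0.63, adjusted p = 0.591) did not pass. No xenobiotic or steroid metabolism gene of 10 measured passed over all genes, and 5 fell adjusted over the list alone (mean -1.30, adjusted p = 3.23e-07, adjusted p = 0.124 with an estimated correlation). The mean was -2.12 without Hnf4a-deleted replicate 5, where the list passed with an estimated correlation too (adjusted p = 0.0328). By fry, which asks whether the genes of a list move one way and compares them with no other genes, the list passed (adjusted p = 0.0473). Ugt2b34 had a log2 fold change of -3.73 (adjusted p = 0.0867) and Akr1c19 one of -3.44 (adjusted p = 0.057). Of 20 fatty acid oxidation and ketogenesis genes, 0 fell over all genes and 1, Bdh1, adjusted over the list alone (mean -0.31, adjusted p = 0.00744, adjusted p = 0.319 with an estimated correlation), and the list was not called in the first prefix (mean 0.04, adjusted p = 0.65). Lists of glycolysis and hypoxia (22 genes, mean -0.16, adjusted p = 0.0715), cell cycle (34 genes, mean -0.15, adjusted p = 0.0982), MAPK output (18 genes, mean 0.28, adjusted p = 0.164) and interferon response (24 genes, mean 0.59, adjusted p = 0.0715) were not called with all 12 libraries and held no changed gene over all genes tested. The cell cycle list was called in opposite directions within the prefixes, with means of 0.45 (adjusted p = 0.000189) and -0.78 (adjusted p = 1.25e-19). It was also called without Hnf4a-positive replicate 3 (mean -0.34, adjusted p = 3.29e-05) or Hnf4a-deleted replicate 3 (mean -0.35, adjusted p = 7.62e-05) and with the pan-epithelial covariate (mean -0.30, adjusted p = 0.00228). The interferon list was called in the first prefix (mean 1.216, adjusted p = 0.000189) but not in the second (mean -0.08, adjusted p = 0.294), and without Hnf4a-positive replicate 4 (0.0185) or 5 (0.031) or Hnf4a-deleted replicate 1 (0.000135) or 6 (0.000583). The glycolysis list was called without Hnf4a-positive replicate 3 or Hnf4a-deleted replicate 2, 5 or 6 (adjusted p 0.0178 to 0.0419), and the MAPK list without Hnf4a-deleted replicate 3 (adjusted p = 0.00809). None of these calls held with an estimated correlation. For cell cycle genes it gave adjusted p = 0.512 and adjusted p = 0.215 within the prefixes, and for interferon genes adjusted p = 0.512 in the first. Etv1, a MAPK output gene, rose adjusted over the list alone (log2 fold change 2.16, SE 0.55, adjusted p over all genes = 0.148).

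Mesenchymal transition genes averaged a log2 fold change of 0.67 over 16 members, of which 0 rose over all genes or adjusted over the list alone. The list test gave adjusted p = 0.00233, and adjusted p = 0.458 with an estimated correlation. The mean was 1.35 in the first prefix and -0.04 in the second, where the list was not called, and fibroblast markers moved with it (1.04 and -0.81). With the acinar covariate the mean was 0.35 and the call ended (adjusted p = 0.266), as it did with the pan-epithelial covariate (mean 0.30, adjusted p = 0.171). Without Hnf4a-deleted replicate 3 the mean was 0.42 (adjusted p = 0.0328). Twist1 had a log2 fold change of 1.76 (SE 0.65, adjusted p = 0.347) and Zeb2 one of 0.65 (SE 0.24, adjusted p = 0.322). Of 7 measured regulators of the sine oculis homeobox and Eya families and their partners, Six4 rose over all genes and adjusted over the list alone (mean 0.75, adjusted p = 0.0316, adjusted p = 0.124 with an estimated correlation, and adjusted p = 0.055 without Hnf4a-deleted replicate 1). By fry the adjusted p was 0.0228. In the second prefix alone the list was not called (mean 1.19, and 0.71 without Six1; adjusted p = 0.061). The mean was 1.39, 1.34, 1.28, 1.34 and 1.29 without Hnf4a-positive replicate 1, 2, 3, 4 and 5, and 1.29 and 1.52 without Hnf4a-deleted replicate 2 and 5. Six1 passes the filter on low counts in these 7 fits, and without it their means were 0.76 to 1.07. Without Hnf4a-positive replicate 1, 2 or 4 or Hnf4a-deleted replicate 5, 9 members were measured, so Six1 was not the only gene to enter. Where Six1 was not tested, the mean was 0.93 without Hnf4a-positive replicate 6. It was 0.67, 1.04, 1.01 and 0.64 without Hnf4a-deleted replicate 1, 3, 4 and 6. With an estimated correlation the list, at 9 measured members, passed without Hnf4a-deleted replicate 5 (adjusted p = 0.0438). The chromatin protein gene Hmga2 had a log2 fold change of 1.01 (SE 0.43, adjusted p = 0.398). The mean of 9 pan-epithelial genes was lowest in Hnf4a-deleted replicates 3 and 6 (4.88 and 5.35 log2 CPM, against 6.19 to 7.82 in the other 10 libraries), and the mesenchymal list was no longer called without these 2 libraries (adjusted p = 0.0996).

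No difference between genotypes was detected in markers of other cell types by an exact permutation test of their mean per library (11 lists, two-sided, adjusted p = 0.722 or more). The test left the prefix out of account, so opposite differences within the prefixes can cancel in it. It does not show that the cell content was equal. Acinar markers showed the largest difference, with a mean log2 CPM of 2.72 ± 2.04 in positive and 0.68 ± 1.81 in deleted tumours (n = 6 each, exact p = 0.0996). Of the 12 measured acinar genes, 0 passed over all genes and 9 fell adjusted over the list alone (list adjusted p = 3.85e-08, adjusted p = 0.208 with an estimated correlation). The carboxypeptidase gene Cpb1 was at 27.7 ± 42.0 CPM in positive and 2.70 ± 2.995 CPM in deleted tumours, with a positive mean of 11.2 CPM without Hnf4a-positive replicate 5. T and NK cell markers had a mean log2 fold change of 1.11 with Trbc2 called among 7 (adjusted p = 0.0316, adjusted p = 0.363 with an estimated correlation), and B and plasma cell markers one of 1.71 with none called among 6 (adjusted p = 0.0358, adjusted p = 0.614 with an estimated correlation). The immunoglobulin light chain gene Igkc ranged from 5.94 to 1075 CPM among the deleted tumours. The T and NK list was not called without Hnf4a-positive replicate 1, 3 or 6 or Hnf4a-deleted replicate 2 or 4, nor the B and plasma list without Hnf4a-positive replicate 1 or Hnf4a-deleted replicate 2, 4 or 5 (adjusted p 0.0523 to 0.312). Without Hnf4a-deleted replicate 2 their means were 0.62 and 0.67. In the second prefix neither list was called (adjusted p = 0.91 and 0.42). With the acinar covariate the T and NK mean was 0.73 (adjusted p = 0.182) and the B and plasma mean 1.87 (adjusted p = 0.243), and with the fibroblast covariate the B and plasma mean was 1.72 (adjusted p = 0.0531), so the B and plasma calls ended without a smaller mean. The list tests of endocrine (adjusted p = 0.0583), macrophage (0.0583), fibroblast (0.984), endothelial (0.933), neutrophil (0.482), erythroid (0.933), adipocyte (0.933) and smooth muscle and mesothelial markers (0.582) did not pass, and for fibroblast and adipocyte markers the mean (0.13 and 0.16) and the test differed in sign. Fibroblast markers were called upward in the first prefix (adjusted p = 8.39e-07) and downward in the second (1.08e-07) and with the acinar covariate (mean -0.35, adjusted p = 0.0128). Endothelial markers were called in the same directions in these 3 fits (adjusted p = 0.000697, 0.00242 and 0.0412). Macrophage markers were called upward in the first prefix (4.08e-05), with the fibroblast covariate (0.0212), with no prefix term (0.0469) and without Hnf4a-positive replicate 4 or 5 or Hnf4a-deleted replicate 1, 4 or 6 (adjusted p 0.00684 to 0.0164). Endocrine markers were called downward with the fibroblast or pan-epithelial covariate (0.0481 and 0.0326) and without Hnf4a-positive replicate 1, 4 or 6 or Hnf4a-deleted replicate 1 or 3 (adjusted p 0.00307 to 0.0385), and adipocyte markers without Hnf4a-positive replicate 1 or Hnf4a-deleted replicate 3 (0.0326 and 0.014). None of these calls held with an estimated correlation, which gave adjusted p = 0.237 and adjusted p = 0.46 for fibroblast and adjusted p = 0.486 and adjusted p = 0.634 for endothelial markers within the prefixes. Only 2 of 14 skeletal muscle markers were measured, Tnni2 (log2 fold change -0.91, adjusted p = 0.507) and Des (0.25, adjusted p = 0.779), and the list was not tested.

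The genotype difference itself differed between the title prefixes for 26 genes (edgeR interaction test), of which 24 encode small or structural RNAs: 9 small nuclear, 7 small nucleolar, 5 miscellaneous and 3 ribosomal RNAs. Except for the pseudogene Rps4l, they were lower in the deleted tumours of the first prefix and higher in those of the second. The largest interaction terms were those of n-R5s205, a copy of the 5S ribosomal RNA gene (log2 6.15, SE 1.06, adjusted p = 0.047), Gm25202, a small nuclear RNA gene (5.82, SE 0.67, adjusted p = 0.0101), Rps4l (-5.61, SE 0.89, adjusted p = 0.0429) and CT010467.1, a ribosomal RNA gene (5.37, SE 0.49, adjusted p = 0.00394). Many such genes have near-identical copies, so their counts are uncertain. As a main effect, 6 of the 16234 genes tested differed between the prefixes, and all 6 were lower in the second prefix. None of the 89 genes changed by genotype was among these 6, which says little with so few.

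**Figure D3:**
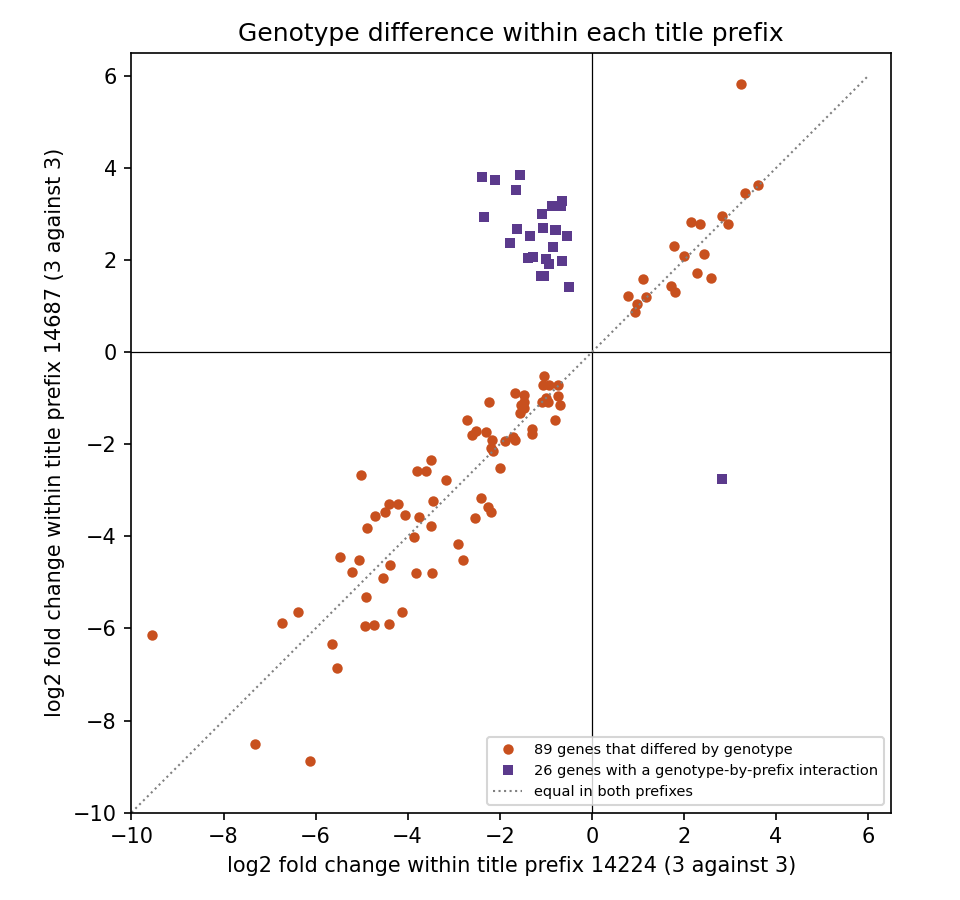
Each point is a gene, with its log2 fold change (Hnf4a-deleted over Hnf4a-positive, 3 against 3 libraries) within the first prefix on the horizontal axis and within the second on the vertical axis; the dotted line marks equal values. All 89 genes changed by genotype have the same sign on both axes, while the 26 interaction genes have opposite signs. Both patterns follow in part from the choice of genes. The 89 were called in a fit of both prefixes together, and the 26 for a difference between them.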

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

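The tests of splits of the libraries were chosen before their results were seen; those of splits balanced over the prefixes, the tests on residual Hnf4a counts, cell composition and small RNAs, and the fit with the pan-epithelial covariate, were chosen after.

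Among 106 groups of 6 libraries examined (named genes, total counts and list means), 7 held a library whose gap to the nearest other was over 0.625 of the group's range. Gap and range were taken on the log2 scale, while levels of single genes are printed below as CPM. Chance alone gives about 1 in 20 groups. Vil1 was at 7.04 CPM in Hnf4a-positive replicate 1, against 82.4 to 132 CPM in the other positive tumours. Sema3d was at 14.8 CPM in Hnf4a-positive replicate 4, against 3.30 to 5.75 CPM in the others. Gata6 was at 37.0 CPM in Hnf4a-deleted replicate 6, against 17.4 to 23.0 CPM. Anks4b was at 0.62 CPM in Hnf4a-deleted replicate 5 and at most 0.0632 CPM in the other deleted tumours. Dnajc22 was at 1.218 CPM in Hnf4a-deleted replicate 2, against 0.126 to 0.344 CPM. The mean of the endodermal transcription factors was 2.82 log2 CPM in Hnf4a-deleted replicate 3, against 3.92 to 4.27. The mean of the cell cycle genes was 3.81 log2 CPM in Hnf4a-positive replicate 3, against 4.64 to 4.94.

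The lower level of 70 genes in the deleted tumours was set against chance and against the cell content of the tumours. Of 100 splits of the 12 libraries into 6 and 6, the real one included, 2 gave 70 or more genes on one side and the same 2 gave 19 or more, and the highest other split gave 154. That split follows the title prefix except that Hnf4a-deleted replicates 3 and 6 change places, so with the prefix in the model it sets each of these 2 libraries against the 5 others of its prefix. Most of these splits are unbalanced over the prefixes and so have less power than the real one. Of 100 splits with 3 libraries of each prefix a side, drawn from 200, 1, the real one, gave as many lower and as many higher genes. The highest other count was 1, so chance is an unlikely source of these numbers. The other splits hold the genotype difference as spread within a side, which lowers their counts. With the pan-epithelial mean as a covariate, the median log2 fold change of the 70 genes moved from -3.01 (median SE 0.43) to -2.86 (0.42). Of them, 53 kept their call, which argues against a lower share of epithelial cells as the whole cause for those 53. The 9 pan-epithelial genes themselves had log2 fold changes of -0.88 to -0.05 (mean -0.44), and 0 were called. With the acinar mean, the median was -2.91 while the median SE grew from 0.43 to 0.51. There 29 of the 70 kept their call, which argues against acinar tissue as the whole cause for those 29. For the 41 others the median went from -2.07 (median SE 0.34) to -1.93 (0.42); the SE grew in all 41 and the fold shrank in 28, in 5 by over its SE, so their calls depend on the model. The 70 genes were called without either covariate. Genes that follow a mean that varies widely within a genotype were unlikely to be among them. The small move of the medians was therefore partly fixed beforehand. A response of the tumour cells to loss of Hnf4a remains a hypothesis, since a change in which epithelial cells were dissected was not tested.

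The number of called lists gave another picture with the preset correlation: 25 of the 100 splits called 13 lists or more (at most 19 in another split), as did 22 of the 100 balanced splits (at most 18 in another), so chance cannot be excluded for that number. With an estimated correlation, 2 of the 100 splits called 5 lists or more, the real one included, and the highest other count was also 5; of the balanced splits 1, the real one, did, and the highest other count was 4. Within the first prefix alone, 10 splits of 6 libraries exist, and 1 of them, the real one, gave 2 genes against a highest other count of 0. In the second, the real split, again 1 of 10, gave 32 genes against a highest other count of 1. These splits are too few for a share under 0.05.

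Hnf4a counts in the deleted tumours were 11.8% of the positive level. If undeleted tumour cells were their only source, HNF4A target genes would keep at least that share. Of 8 measured target genes at 10 CPM or more in positive tumours, 5 kept less than Hnf4a by over 2 SE of the difference: Apob 0.414%, Anks4b 0.916%, Vil1 1.59%, Lgals4 3.18% and Hnf1a 3.77%. Undeleted tumour cells as the only source therefore do not account for the remaining counts, unless such cells lacked these transcripts for another reason. Cells other than tumour cells in the dissected tissue were not tested as a source. Such cells could hold Hnf4a transcripts without those of the 5 target genes. Transcripts from exons outside the deleted part may add to them, which gene-level counts cannot test.

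The genotype difference of 26 genes differed between the title prefixes by an interaction test, and 24 of the 26 are small or structural RNAs. Of 100 relabellings within the prefixes, 2 gave 26 genes or more, the real one included; the other, with 96 genes, exchanges the genotypes within one prefix, which turns the interaction term into the genotype difference itself. Over all 141 small nuclear and nucleolar RNA genes tested, the median log2 fold change was -0.63 in the first prefix and 1.07 in the second. These RNAs took 0.548% to 0.608% of the counts in the 3 deleted libraries of the second prefix. They took at most 0.224% in those of the first and at most 0.311% in any positive library, which argues against loss of Hnf4a as the whole cause. A difference in the handling of those 3 libraries and an effect of genotype present only in the second prefix cannot be told apart. The 3 libraries share both, and no positive library reaches their level (0.311% against 0.548%). Their sample titles are also the only ones that end in P2. The titles of the deleted libraries carry the letters HC in the first prefix and ES in the second. What these marks stand for is not stated.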

How the results depend on the processing

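Counts of changed genes depended on the method more than their direction did. Of 19 higher and 70 lower genes, the numbers became 210 and 313 with DESeq2 (59.8% lower, against 78.7%), which kept 18 and 70 of them; 2 and 36 with the test against a 1.5-fold change; 1 and 29 with the acinar covariate (96.7% lower); 0 and 2 in the first prefix alone; and 12 and 43 without Hnf4a-deleted replicates 3 and 6 (added after seeing the data). Higher genes numbered 12 with the stricter filter and 12 with the pan-epithelial covariate (added later), and lower genes 16 in the second prefix alone. Fits within prefixes have fewer libraries and so less power, but the cause of the losses was not tested, there or elsewhere. Leaving out single libraries gave 1 to 29 higher and 41 to 107 lower genes. The other scalings gave 18 higher genes each and 64 (upper quartile) or 72 (size factors) lower ones. No scaling moved the median of all genes by over 0.1, but each scaling centres most genes, so that median says little. The 20 genes with the largest changes, chosen for the same sign within both prefixes, kept their sign in every fit that tested them. Hnf4a stayed between -2.58 and -3.61 on the log2 scale in all 28 alternatives; the first prefix alone gave -3.61 and missed the threshold (adjusted p = 0.0865, against 5.42e-20 to 0.0285 in the rest). Leaving out single libraries gave -3.27 to -2.87. The interaction count of 26 became 50 without a filter, 14 with the stricter filter and 0 among protein-coding genes only (edgeR, all added later), where the small RNAs are not tested. Across named genes and alternatives, 3089 outcomes (called or not) were the same, 188 calls were lost, 26 gained and 0 reversed. A gene or list called in neither fit counted as the same, even where its sign changed. Many named genes were of this kind, such as Foxa1, called in 0 of 28 alternatives with log2 fold changes of -0.33 to 0.95. The count of unchanged outcomes therefore says little about how stable the calls were. With an estimated correlation (added later outside the fit of all libraries), 498 list outcomes were the same, 9 lost and 2 gained, and none of 45 calls gained with the preset correlation held (lowest adjusted p 0.0974). Across lists with the preset correlation, 479 were the same, 37 lost, 41 gained and 6 reversed. The reversed list tests, for which the cause was not tested, had means of -0.042 for mesenchymal genes in the second prefix, 0.45 for cell cycle genes in the first, -0.30 and -0.47 for endothelial markers with the acinar covariate and in the second prefix, 1.04 for fibroblast markers in the first and 0.10 for T and NK cell markers in the second. In the last 2 only the test changed direction. The fibroblast mean itself, 0.13 over all libraries with the test pointing down, was -0.81 in the second prefix and -0.35 with the acinar covariate. The 22 marker comparisons with another prior count or without TMM kept their outcome. Six1, with 2 to 23 counts in positive and 7 to 785 in deleted tumours, was tested only in some fits. It entered the fits without a filter (log2 fold change 4.75, SE 1.28, adjusted p = 0.326), of the second prefix alone (4.54, adjusted p = 0.435) and without any of 7 single libraries (4.52 to 5.10, adjusted p 0.0554 to 0.251), and passed the threshold in none. Labels share no replicate numbers, so no paired analysis was possible because nothing pairs the samples.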

Other observations

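Six1 and Six4 are neighbours on chromosome 12 (Six1 at 73040015 to 73053887 and Six4 at 73099609 to 73113456 in GENCODE M21 on GRCm38), and their high values fell in the same deleted tumours. In Hnf4a-deleted replicates 1, 3 and 6, Six4 was at 41.0, 80.2 and 115 CPM and Six1 at 6.93, 19.7 and 49.6 CPM. In replicates 2, 4 and 5, Six4 was at 16.02, 14.6 and 13.1 CPM and Six1 at 0.66, 0.93 and 0.48 CPM. Replicates 1, 3 and 6 were also the deleted libraries with the lowest means of the 9 pan-epithelial genes (6.43, 4.88 and 5.35 log2 CPM, against 7.18 to 7.82). Because the values fall in separate sets, no correlation is given. Eya1, which encodes a partner of sine oculis proteins and was chosen after its values were seen, was at 47.9 CPM in Hnf4a-deleted replicate 6, at 8.10 CPM in replicate 1 and at 0.41 CPM in replicate 3, so it did not follow Six4 in each of the 3.

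Stromal and proliferation lists had means of opposite sign within the prefixes. From the first to the second prefix, the mean log2 fold change was 1.04 and -0.81 for fibroblast markers, 0.67 and -0.47 for endothelial markers and 0.45 and -0.78 for cell cycle genes. The difference between prefixes was not tested for the lists.

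Hnf1aos1, an RNA antisense to Hnf1a and chosen after its values were seen, was also lower in the deleted tumours (log2 fold change -3.65, adjusted p = 0.0451). The strand setting of the counting is not given in the sources used here, so the reads of the pair cannot be told apart without it. Gm14236, also chosen after its values were seen, was 6.42 log2 units lower in the second prefix than in the first, the largest of the 6 prefix differences, and took 0.34% to 1.30% of the counts in the first prefix and at most 0.0264% in the second.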
